A study of Homo sapiens with 16 samples.

How the data were processed

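The series holds 16 Human Transcriptome Array 2.0 hybridizations of human total RNA. Blood RNA, collected and extracted with PAXgene reagents per the labels' protocols, and bought brain RNA were used alone and in 2 mixtures, with 67% blood and 33% brain or 33% blood and 67% brain. Each of the 4 mixtures was amplified with 2 kits, GeneChip WT PLUS from Affymetrix and Ovation Pico WTA System V2 from NuGEN, in 2 replicates, so each kit has 8 arrays. The labels give group and replicate of every array. Nothing in them says that replicates came from separate donors or extractions, so the p-values measure only the spread between these arrays, which may be technical. The number of arrays limits the precision of each value.

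The deposited table gives 1 value per feature and array, running from 0.813 to 13.88. The authors deposited log2 values; the base was inferred from that range and is not stated in the table. Per the series' design text the arrays of the 2 kits were normalized separately. Background correction, normalization and summarization methods are not given in the sources used here. The submitters' processing notes name the genome build hg19 and limma, without versions. The deposited values differ in distribution between arrays of a kit. Whether a common distribution was forced on them at an earlier step is not known. Because of the separate normalization every test was made within a kit, and the kits were compared only through the difference of their within-kit changes.

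Of 70523 features, the 67528 transcript clusters were tested and 2995 others were left out, among them 92 ERCC spike-in features, 23 antigenomic background features, which match no human sequence, and 4 hybridization controls. In the platform annotation 23781 tested features have 1 gene symbol, 1543 have several and 42204 are unnamed here. A gene was named only from features with 1 symbol, which left 22465 genes. Updating symbols through Entrez identifiers in a RefSeq table for assembly GRCh38.p14 changed 0 of them. That table is of another build than hg19, so no coordinates are given. A gene with several features was represented by the one with the highest mean, and 1540 tested features lie on alternative haplotypes or unplaced contigs. The globin genes on features with several symbols, and the mitochondrially encoded genes, are not reported.

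Linear models were fitted with limma 3.58.1 in R 4.3.3 to the values as deposited, with 1 coefficient per mixture and 8 arrays per kit, and moderated by empirical Bayes. The residual degrees of freedom were 4 per kit. A joint model of the 16 arrays tested whether the change from all blood to all brain differed between the kits. P-values were adjusted over the 67528 features with the Benjamini-Hochberg method, and an adjusted p under 0.05 was called a change. All p-values are two-sided limma values. Each of the 6 contrasts of a kit, and the difference between kits, was adjusted on its own.

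Of 30 gene lists written before the data were examined (cell types of brain and blood, brain regions, and general gene groups), 29 had at least 3 measured genes. They were tested with camera from limma at a preset correlation between genes of 0.01, on 1 feature per gene, and adjusted over the 29 lists. Each list was tested again with a correlation estimated from the arrays. With that estimate 0 of the 29 lists passed in either kit or in the difference between them. In that mode camera takes its p-values from the residual degrees of freedom, 4 in the fit of a kit, so small p-values are hard to reach at any correlation. For B cells with WT PLUS the estimate was −0.031, under the preset 0.01, yet the adjusted p went from 2.19e-05 to 0.0835. A list that does not pass there is therefore not shown to owe its call to correlated genes. Only 1 gene is in more than 1 list.

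Genes were named by a rule also fixed beforehand. It takes, per kit, the 6 largest rises and 6 largest falls from blood to brain among named genes that passed the test with non-overlapping arrays. It also takes the 6 largest differences between kits in each direction, and 2 members of each list. These 2 have the largest absolute value of the mean change over the 2 kits, which favours genes that change the same way in both. Every member of the globin, housekeeping and brain region lists was eligible too. Uncharacterised loci, small RNAs outside their list, immune receptor segments and genes that reflect donor sex were skipped.

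The brain share of a mixture was estimated on the linear scale. For features at least 4-fold apart between blood and brain, the mixture's signal was placed between those of the all-blood and all-brain arrays, separately for brain-high and blood-high features. The median of each set was taken and both were averaged. Mixture order is the percent of features, among those past the threshold and at least 2-fold apart between blood and brain, whose change from the 67% to the 33% blood mixture has the sign of their brain minus blood change. The slope of Ovation Pico on WT PLUS changes is orthogonal, with error allowed in both.

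The brain minus blood test, the test of the difference between kits, the brain share estimate and 1 shifted gene list were tested on simulated data. These held 67528 features, drawn independently and without a shift of whole arrays. The other mixture contrasts, mixture order, slope, overlap between kits and later tests were not simulated. With the neuron list shifted by a log2 value of 1 with Ovation Pico, camera called that list and no other in the difference. With 100 features changed by a log2 value of 1, the brain minus blood test called 66 with WT PLUS and 30 with Ovation Pico, and the test of the difference between kits called 45. At a log2 change of 2 these numbers were 96, 82 and 93. Unchanged features called were 5, 2 and 1. The simulation was accepted at 75 or more of 100 recovered at a log2 change of 2, a level lowered after Ovation Pico had missed a stricter one. Simulated mixtures of 33% and 67% brain were returned as 33.1% to 33.2% and 66.6% to 66.7% with WT PLUS, and as 34.8% to 35.1% and 67.4% to 67.6% with Ovation Pico.

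The alternatives were the brighter 50% of features, quantile normalization of a kit's arrays, centring on housekeeping genes, trended and robust empirical Bayes, fits on fewer or more arrays, the replicate number as a block, a 2-fold minimum, features with 1 symbol, and each array left out in turn. Others were chosen after seeing the data: the arrays without hybridization control signal as a block, the brightest 25% of features, and arrays left out for the brain share. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.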

Results

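RNA from human blood, from human brain and from 2 mixtures of both was amplified with the GeneChip WT PLUS or the Ovation Pico kit and hybridized to Human Transcriptome Array 2.0 chips. Groups had 2 arrays each, 16 in all. The median log2 signal of replicates 1 and 2 with WT PLUS was 4.09 and 4.08 for all blood, 3.91 and 3.89 for 67% blood, 3.90 and 3.82 for 33% blood, and 3.81 and 3.87 for all brain. With Ovation Pico it was 3.33 and 3.16 for all blood, 3.09 and 3.16 for 67% blood, 3.08 and 3.18 for 33% blood, and 3.14 and 3.12 for all brain. The kits were normalized apart, so levels were not compared between them. Changes are log2 differences ± SE from limma, with 2 arrays against 2, and levels are means ± SD (n = 2).

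The first comparison asked which genes differ between brain and blood RNA with the WT PLUS kit. The largest named rises in brain were mostly in neural genes. SPARCL1, a matrix protein of astrocytes, rose by 6.41 ± 0.121, from a log2 signal of 3.72 ± 0.0607 to 10.12 ± 0.166 (adjusted p = 3.86e-08). KIF5A, a neuronal kinesin, rose by 6.13 ± 0.153, ATRNL1 by 6.02 ± 0.106, STMN2, a regulator of axonal microtubules, by 5.75 ± 0.158, SPP1, which encodes osteopontin, by 5.66 ± 0.138 and the neurofilament gene INA by 5.63 ± 0.184. The largest falls were in blood cell genes. LYZ, the lysozyme of myeloid cells, fell by 7.75 ± 0.122 on the log2 scale, from 11.86 ± 0.0371 to 4.11 ± 0.134, a lower bound, since it was still at 11.20 with 33% blood. ALAS2, the first enzyme of heme synthesis in red cells, fell by 6.81 ± 0.0956, the interleukin receptor gene IL7R of T cells by 6.08 ± 0.123, the platelet chemokine PPBP by 6.07 ± 0.116, AQP9 by 5.65 ± 0.149 and MNDA, a nuclear antigen of myeloid cells, by 5.60 ± 0.133. All 12 had adjusted p of at most 1.61e-07. In the tissue with less signal, SPARCL1, ATRNL1 (2.89), SPP1 (3.81) and INA (4.10) in blood and IL7R (3.01), PPBP (2.62), AQP9 (3.00) and MNDA (3.79) in brain lay under the mean of the 23 antigenomic background features on both arrays (4.23 and 4.30 in blood, 3.92 and 3.98 in brain). They are not shown to be above background there, so these changes are taken as lower bounds and the order of the genes is uncertain. Of the genes picked by the naming rule, this applies to 38 of 111 that changed with WT PLUS and 15 of 88 that changed with Ovation Pico. With WT PLUS they include GRIA2, RELN, AQP4, UGT8, LHFPL3, CA8, GABRA6, PDE10A and SNORD115-10 in blood, and CXCR2, CD2, MS4A1, GZMA, KLRB1, CLC and HBD in brain, whose changes below are taken as lower bounds as well. The antigenomic mean is only a rough limit. It spans features with 3 to 25 G and C bases, at 1.65 to 11.71 on WT PLUS all blood replicate 1. It also lies above the median of the tested features on the WT PLUS all-blood arrays (4.03 and 4.02). A gene above that mean is therefore not shown to be above its own background, nor a gene under it to be at background.

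Neuronal and macroglial lists were higher in brain with WT PLUS, but none passed with an estimated correlation, where the adjusted p = 0.0835 for glutamatergic, GABAergic, astrocyte and oligodendrocyte genes. All 19 measured neuron genes rose, with a median of 3.21 (adjusted p = 6.57e-15 by camera, adjusted p = 0.104 with an estimated correlation), NEFL by 5.53 and STMN2 by 5.75. All 13 glutamatergic genes rose (median 2.27, adjusted p = 4.05e-10), among them the AMPA receptor subunit GRIA2 at 4.84 and the kinase CAMK2A at 4.15. Of 13 GABAergic genes 9 rose and 1 fell (median 1.13, adjusted p = 5.47e-05), with RELN at 4.71 and the calcium buffer PVALB at 2.76. Of 12 astrocyte genes 11 rose (median 2.81, adjusted p = 1.27e-08), among them the water channel AQP4 at 5.08 and ALDOC at 4.16. Of 14 oligodendrocyte and myelin genes 12 rose, or 13 adjusted over the list alone (median 1.34, adjusted p = 4.52e-08), with the myelin protein MOBP at 3.74 and UGT8, an enzyme of myelin lipids, at 3.62. Of 8 oligodendrocyte precursor genes 5 rose and 2 fell (median 0.65, adjusted p = 0.00904, and adjusted p = 0.0844 with an estimated correlation), with TNR at 3.26 and LHFPL3 at 1.65. Of 12 vessel genes 6 rose and 1 fell (median 0.28, adjusted p = 0.0115, and adjusted p = 0.0887 with an estimated correlation). The pericyte gene RGS5 rose by 2.28, while PECAM1, which blood cells also express, fell by 2.94. The microglia list did not pass (4 rose, 5 fell, median −0.15, adjusted p = 0.441). Its largest members were TYROBP at −3.93 and CD68 at −2.19, both also expressed by blood myeloid cells. Adjusting over each list alone left the other counts as given.

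Among the brain region lists, 10 of 11 cerebellar genes rose with WT PLUS (median 1.95, adjusted p = 1.05e-06, and adjusted p = 0.0835 with an estimated correlation). GABRA6, a receptor subunit of granule cells, rose by 3.38, CA8 by 2.05, the synaptic organizer CBLN1 by 2.04 and ZIC1 by 2.02, and the Purkinje cell gene PCP2 was at −0.32, called as lower only when adjusted over the list alone. Of 9 striatal genes 4 rose and 1 fell, and the list did not pass (median 0.13, adjusted p = 0.0736). PDE10A rose by 2.15, while ADORA2A fell by 0.86. All 9 genes of brainstem monoamine and acetylcholine neurons had lower signals in brain and 8 fell (median −0.35, adjusted p = 0.0440, and adjusted p = 0.477 with an estimated correlation). TH, the first enzyme of dopamine synthesis, fell by 0.47 ± 0.0922, where the median change of all features was −0.22. An antigenomic background feature of similar signal, with 19 G and C bases, fell by 0.654. It was at 5.33 and 5.42 on the brain arrays, and TH at 5.285 there. Falls of this size in the brainstem list are therefore not shown to be falls of its RNAs. The list did not pass with quantile normalization, with housekeeping centring, or without either all-blood array, either 67% blood array or all brain replicate 1. Of 9 hypothalamic peptide genes 7 fell, but the list did not pass (median −0.39, adjusted p = 0.123), and OXT was at −0.39. These falls carry the same limit as those of the brainstem genes. Of 7 choroid plexus and ependyma genes 1 rose and 1 fell, or 3 and 2 adjusted over the list alone (median −0.03, mean 0.40, camera direction up, adjusted p = 0.441). The gene that rose, by 3.15, was TTR, the thyroid hormone carrier made by choroid plexus, and FOXJ1 fell by 0.51.

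Blood lists were lower in brain with WT PLUS, but none passed with an estimated correlation, where the adjusted p = 0.0835 for the 8 lists other than globins. All 17 neutrophil genes fell (median −4.39, adjusted p = 3.13e-10), among them MNDA by 5.60 and the chemokine receptor CXCR2 by 5.56. All 16 T cell genes fell (median −2.56, adjusted p = 1.27e-08), with CD2 at −4.02, as did all 12 natural killer and cytotoxic genes (median −2.66, adjusted p = 3.49e-07), with KLRB1 at −3.97 and the granzyme GZMA at −3.40. All 10 B cell genes fell (median −1.50, adjusted p = 2.19e-05), MS4A1 by 3.75 and CD79A by 2.91, and all 11 platelet genes (median −1.45, adjusted p = 1.06e-05), PF4 by 3.31. All 7 eosinophil and basophil genes fell (median −0.98, adjusted p = 0.00173), CLC by 5.03. Of 11 monocyte genes 10 fell (median −2.62, adjusted p = 1.05e-06), with CTSS at −4.26, and of 12 red cell precursor genes without globins 11 fell (median −2.06, adjusted p = 1.75e-05), with the anion exchanger SLC4A1 at −4.34. Adjusting over each list alone added 1 rise, in the red cell list. All 5 measured globins fell (median −2.09, adjusted p = 0.00173, and adjusted p = 0.193 with an estimated correlation). HBB fell by 4.76, a lower bound since its signal hardly moved while any blood was present, HBM by 2.31, HBZ by 2.09, HBQ1 by 1.31 and HBD by 1.16.

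General gene groups also differed with WT PLUS. All 17 nuclear genes of oxidative phosphorylation rose (median 0.98, adjusted p = 1.27e-08, and adjusted p = 0.0835 with an estimated correlation), CYCS by 2.46 and NDUFS1 by 1.81. Of 14 interferon response genes 11 fell and 1 rose, or 12 and 1 adjusted over the list alone (median −0.83, adjusted p = 0.000657, and adjusted p = 0.0835 with an estimated correlation), with OAS2 at −2.53 and MX2 at −2.25. Of 18 ribosomal protein genes 12 fell, or 12 with 1 rise adjusted over the list alone (median −0.45, adjusted p = 0.0197, and adjusted p = 0.384 with an estimated correlation), with RPS19 at −1.06 and RPS16 at −0.95, and the list did not pass without all brain replicate 2. Of 12 histone genes 8 fell and 1 rose (median −0.75, adjusted p = 0.0243, and adjusted p = 0.342 with an estimated correlation), with H2BC12 at −2.38 and H2AC6 at −1.66. The immediate early genes did not pass (2 rose, 4 fell, median −0.06, mean −0.04, camera direction up, adjusted p = 0.908). EGR1 rose by 1.93 and JUNB fell by 1.38. Of 237 small nucleolar RNAs 94 rose and 74 fell, or 97 and 80 adjusted over the list alone (median 0.02, mean 0.87, adjusted p = 0.00189, and adjusted p = 0.583 with an estimated correlation). The median was −0.15 with housekeeping centring, −0.03 without all brain replicate 2 and 0.29 (adjusted p = 6.27e-07) with the arrays without hybridization control signal as a block. SNORD115-10 rose by 7.85 and SNORD115-6 by 7.74, 2 of a family of near-identical copies whose signals are not separable with certainty. The housekeeping genes did not pass as a list (median 0.33, adjusted p = 0.0944), but B2M fell by 2.19 and HPRT1 rose by 2.04.

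In all, 34811 of 67528 features changed between brain and blood with WT PLUS, 8919 higher and 25892 lower in brain (74.4% lower). At least 2-fold changes were 3620 higher and 3992 lower. Quantile normalization gave 51.8% lower and housekeeping centring 85.8% lower, and moved the median change of all features from −0.22 to −0.04 and −0.40. The 4 hybridization controls, added before hybridization, had a mean log2 signal of 11.4 to 11.8 on 5 WT PLUS arrays, but 3.25 on 33% blood replicate 2 and 3.41 and 3.07 on all brain replicates 1 and 2. Only the 33% blood group spans both kinds of array, so brain and blood do not share a kind. With the kind of array as a block, 11947 features changed, 5006 higher and 6941 lower (58.1% lower), and 22 of the 23 lists that passed still passed, the brainstem list being the exception. None of the brainstem and hypothalamic genes called as lower passed with it, nor did FOXJ1. Of the other genes named for their brain minus blood change or their list, EN2, DRD1, PPP1R1B, ACTB, GUSB, PGK1, POLR2A, SDHA and TFRC did not pass either. ACTB and GUSB had been lower and the others higher. Outside the globin, housekeeping and region lists, only the named members of a list were checked with the block. The median with that block was 3.20 for neurons, 2.70 for astrocytes, 1.72 for cerebellum and −4.49 for neutrophils. Within the arrays with controls, 33% blood replicate 1 minus all blood gave 2.84, 2.44, 1.56 and −1.30 for these lists, and 18348 changed features. Within the arrays without them, all brain minus 33% blood replicate 2 gave 0.25, 0.26, 0.25 and −3.01, and 1394 changed features. Without all brain replicate 1, 22100 features changed between brain and blood.

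**Figure D1:**
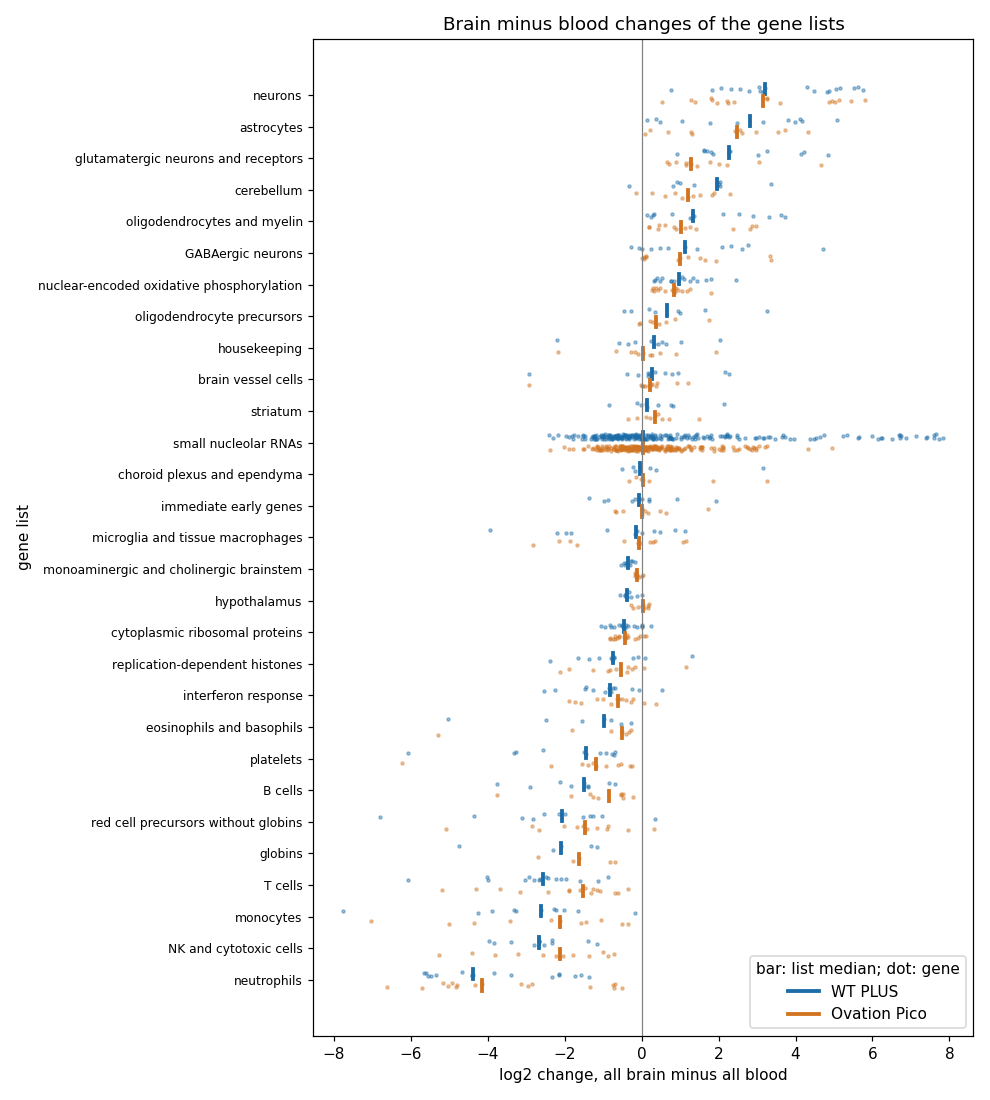
Log2 change from all blood to all brain of the genes of 29 lists (dots) and of the list median (bars) with WT PLUS and Ovation Pico, ordered by the WT PLUS median. Medians run from −4.39 for neutrophils to 3.21 for neurons with WT PLUS, and from −4.16 to 3.15 with Ovation Pico.

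The same comparison with Ovation Pico again put mostly neural genes first. SPARCL1 rose by 6.48 ± 0.158, from 2.62 ± 0.290 to 9.09 ± 0.0365 (adjusted p = 3.41e-06). ATP1B2, a sodium pump subunit of glia, rose by 5.92 ± 0.202. The neurofilament genes NEFM and NEFL rose by 5.82 ± 0.144 and 5.44 ± 0.185. PMP2, a lipid-binding myelin protein, rose by 5.66 ± 0.187, and HEPN1 by 5.46 ± 0.164. HEPN1 is not counted as neural here, and its rise was 4.49 larger than with WT PLUS. Among the largest changes in the other direction, LYZ fell by 7.04 ± 0.203, MNDA fell by 6.63 ± 0.186, PPBP by 6.23 ± 0.286, PTPRC, the common leukocyte antigen CD45, by 6.19 ± 0.204, EVI2B by 5.80 ± 0.184 and the neutrophil calcium-binding protein S100A12 by 5.70 ± 0.277. All 12 had adjusted p of at most 2.36e-05. SPARCL1 and PMP2 (2.10) in blood and PPBP (2.45) and S100A12 (2.32) in brain lay under the antigenomic mean of both arrays (2.92 and 2.65 in blood, 2.76 and 2.68 in brain), so their changes are lower bounds, as is that of LYZ, which was still at 10.03 with 33% blood.

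Brain cell lists were higher with Ovation Pico too. All 19 neuron genes (median 3.15, adjusted p = 1.67e-21, and adjusted p = 0.124 with an estimated correlation) and all 13 glutamatergic genes (median 1.28, adjusted p = 6.41e-11, and adjusted p = 0.164 with an estimated correlation) rose. So did 8 of 13 GABAergic genes (median 1.00, adjusted p = 1.27e-05, and adjusted p = 0.264 with an estimated correlation), 10 of 12 astrocyte genes (median 2.49, adjusted p = 1.19e-10) and 10 of 14 oligodendrocyte genes, or 12 adjusted over the list alone (median 1.01, adjusted p = 1.64e-09). The last 2 lists had adjusted p = 0.128 with an estimated correlation. Of 8 precursor genes 3 rose (median 0.38, adjusted p = 0.0106, and adjusted p = 0.398 with an estimated correlation), and 8 of 11 cerebellar genes, or 9 adjusted over the list alone (median 1.21, adjusted p = 2.89e-06, and adjusted p = 0.164 with an estimated correlation), CA8 by 2.31 and GABRA6 by 1.89. Of 9 striatal genes 3 rose (median 0.34, adjusted p = 0.0446, and adjusted p = 0.508 with an estimated correlation), PDE10A by 1.49, PPP1R1B by 0.72 and TAC1 by 0.52. The striatal list did not pass with housekeeping centring, without all blood replicate 2 or without all brain replicate 2, and PPP1R1B and TAC1 did not pass without either all-brain array. Vessel genes (2 rose, or 3 adjusted over the list alone, and 1 fell, median 0.23, adjusted p = 0.106), microglia (2 rose, 5 fell, median −0.06, adjusted p = 0.329), brainstem (0 changed, median −0.13, adjusted p = 0.582) and hypothalamus (0 changed, median 0.04, adjusted p = 0.786) did not pass. Choroid plexus and ependyma did not either (median 0.05, adjusted p = 0.133), with 2 rises, TTR by 3.26 and CFAP126, a gene of motile cilia, by 1.85.

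Blood cell lists were lower with Ovation Pico, but none passed with an estimated correlation, where the adjusted p ran from 0.124 to 0.166 for the 8 lists other than globins. All 17 neutrophil genes (median −4.16, adjusted p = 5.19e-16) and all 12 natural killer and cytotoxic genes (median −2.13, adjusted p = 7.46e-11) fell, and 15 of 16 T cell genes, or 16 adjusted over the list alone (median −1.54, adjusted p = 3.34e-12). Of 11 monocyte genes 9 fell, or 11 adjusted over the list alone (median −2.13, adjusted p = 1.76e-09), of 12 red cell precursor genes 10 (median −1.48, adjusted p = 3.17e-07), of 11 platelet genes 9 (median −1.20, adjusted p = 8.20e-07), of 10 B cell genes 7, or 8 adjusted over the list alone (median −0.84, adjusted p = 5.84e-06), and of 7 eosinophil and basophil genes 5 (median −0.51, adjusted p = 0.000626). Of 5 globins 4 fell, or 5 adjusted over the list alone (median −1.62, adjusted p = 5.97e-05, and adjusted p = 0.127 with an estimated correlation), HBB by 2.69 as a lower bound and HBD by 1.62, while HBQ1 was at −0.70. Of 14 interferon response genes 10 fell (median −0.61, adjusted p = 0.000133, and adjusted p = 0.166 with an estimated correlation), of 18 ribosomal protein genes 7, or 9 adjusted over the list alone (median −0.44, adjusted p = 0.000724, and adjusted p = 0.449 with an estimated correlation), and of 12 histone genes 5 fell and 1 rose (median −0.52, adjusted p = 0.00616, and adjusted p = 0.327 with an estimated correlation). Without all blood replicate 2 the oligodendrocyte precursor, ribosomal and histone lists did not pass. Of 17 oxidative phosphorylation genes 11 rose, or 16 adjusted over the list alone (median 0.85, adjusted p = 8.30e-08, and adjusted p = 0.166 with an estimated correlation). Small nucleolar RNAs (68 rose, 23 fell, or 73 and 34 adjusted over the list alone, median 0.03, adjusted p = 0.0545), immediate early genes (3 rose, 3 fell, median 0.01, adjusted p = 0.582) and housekeeping genes (2 rose, 2 fell, median 0.05, adjusted p = 0.867) did not pass. Among housekeeping genes ACTB fell by 0.67 and B2M by 2.18, and GAPDH rose by 0.89 and HPRT1 by 1.92. ACTB and GAPDH did not pass without either all-brain array.

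With Ovation Pico 11774 features changed between brain and blood, 5159 higher and 6615 lower (56.2% lower), and 2717 were at least 2-fold higher and 3316 at least 2-fold lower. Quantile normalization gave 45.8% lower and housekeeping centring 59.5% lower. The fit of these 4 arrays alone called 7163 features, and leaving out all brain replicate 1 or 2 left 6088 or 6153. The all-blood replicates differed most: the SD of their difference over features was 0.431 (r = 0.965 across features, which are not independent replicates), against 0.264, 0.233 and 0.182 for 67% blood, 33% blood and all brain. With WT PLUS these SDs were 0.213, 0.184, 0.210 and 0.193. The median residual SD of a feature was 0.107 with WT PLUS and 0.157 with Ovation Pico.

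Along the mixtures, the largest log2 step of the brain-high genes shown was the first, and that of the blood-high genes shown the last. Steps on the linear scale have other sizes. With WT PLUS SPARCL1 went from 3.72 in blood to 9.08 ± 0.0726 at 33% brain, 9.78 ± 0.193 at 67% and 10.12 in brain, and KIF5A from 4.39 to 9.49, 10.17 and 10.51. With Ovation Pico SPARCL1 went from 2.62 to 8.63 ± 0.107, 8.94 ± 0.114 and 9.09. LYZ was at 11.86, 11.61, 11.20 and 4.11 in the same order with WT PLUS, and at 11.10, 10.74, 10.03 and 4.07 with Ovation Pico. PPBP was at 8.70, 8.03, 6.84 and 2.62 with WT PLUS. HBB was nearly flat while any blood was present: 11.64 ± 0.0444, 11.60 ± 0.0704 and 11.42 ± 0.0334 before 6.89 ± 0.102 in brain with WT PLUS, and 11.64 ± 0.00986, 11.61 ± 0.00174 and 11.48 ± 0.0371 before 8.94 ± 0.388 with Ovation Pico. Its falls from blood to brain are therefore lower bounds with both kits.

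**Figure D2:**
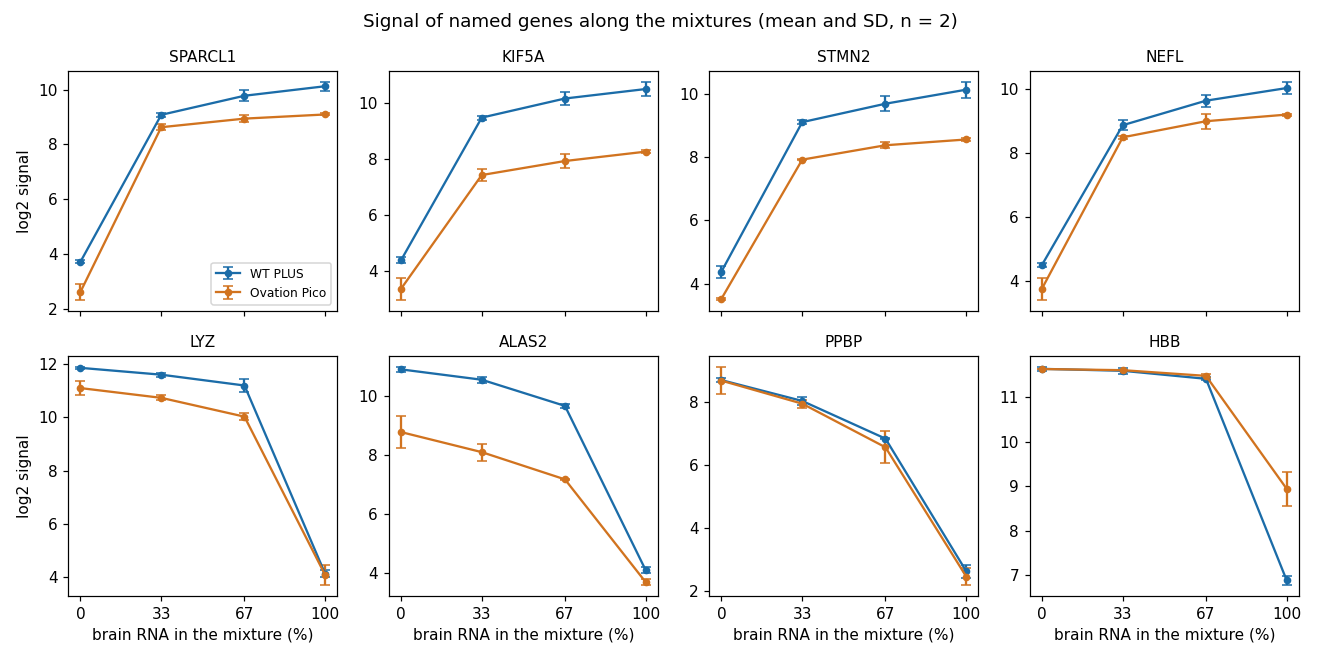
Mean log2 signal (± SD, n = 2) of 4 brain-high and 4 blood-high genes against the percent of brain RNA for each kit; vertical axes differ between genes and do not start at 0. SPARCL1 rises to 9.08 at 33% brain with WT PLUS, and HBB stays at 11.42 or above until blood is gone.

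Counts of changed features were taken for each step. From all blood to 67% blood, 20251 features changed with WT PLUS, 4694 higher and 15557 lower (76.8%, and 52.7% of 11826 with quantile normalization), but at least 2-fold changes were 1698 higher and 201 lower. Mixing the mean blood and brain signals of each feature at the labelled shares would give 1287 and 0 without regard to significance, and an SD of log2 changes of 0.351 where 0.468 was observed. The observed SD includes noise of the mixture arrays and the calculated one does not, so the excess is not all shown to be a departure from the labelled shares. Leaving out all blood replicate 1 or 2 left 13272 or 10170 (71.8% or 65.2% lower), and leaving out 67% blood replicate 1 or 2 left 7731 or 8568 (59.3% or 61.6% lower). From 67% to 33% blood 2640 features changed, 763 higher and 1877 lower. That count was 167 without 67% blood replicate 1, 0 without 67% blood replicate 2, 1481 without 33% blood replicate 1 and 731 without 33% blood replicate 2. From 33% blood to all brain 1908 changed, 137 higher and 1771 lower, of which 2 and 816 at least 2-fold, against 0 and 1258 from mixing. Over the wider steps, 32983 changed from all blood to 33% blood, 7032 higher and 25951 lower (78.7%, and 55.5% of 20192 with quantile normalization), or 18348 without 33% blood replicate 2. From 67% blood to all brain 10977 changed, 5749 higher and 5228 lower (47.6% lower), of which 367 and 1874 at least 2-fold. Without 67% blood replicate 1 or 2 or all brain replicate 1 that was 6852, 7109 or 6504, and the majority was then lower (53.4%, 54.0% and 55.8%).

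With Ovation Pico 3013 features changed from all blood to 67% blood, 2118 higher and 895 lower. At least 2-fold changes were 1438 higher and 206 lower, against 903 and 0 from mixing, and the SD was 0.465 against 0.291, again with noise of the mixture arrays in the first value only. That excess of higher features depends on the all-blood arrays: without replicate 1 of them 2640 were higher and 3629 lower (6269 in all), and without replicate 2, 4419 and 9322 (13741 in all). The count was 1132 and 1334 without 67% blood replicate 1 and 2, and 1759 without either all-brain array. From 67% to 33% blood limma called 0, with 4418 features at an unadjusted p under 0.05, and 271 without either all-blood array. From 33% blood to all brain 145 changed, 2 higher and 143 lower, all at least 2-fold, against 0 and 918 from mixing. That was 600 without either all-blood array, 94 without either 67% blood array, and 17 to 34 without 1 of the 4 arrays compared. From all blood to 33% blood 8803 changed, 3906 higher and 4897 lower (55.6%, and 44.1% with quantile normalization), or 15992 without all blood replicate 2 (67.4% lower) and 3003 and 3653 without 33% blood replicate 1 and 2 (40.5% and 36.2% lower). From 67% blood to all brain 1303 changed, 137 higher and 1166 lower (89.5%, and 74.4% with quantile normalization). It was 4497 without either all-blood array, 639 without either 33% blood array, 228 and 426 without 67% blood replicate 1 and 2, and 224 and 255 without all brain replicate 1 and 2.

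Most features that differed at least 2-fold between brain and blood also moved the same way from 67% to 33% blood. This held for 98.8% of 7612 features with WT PLUS and 95.9% of 6033 with Ovation Pico. Single pairs of arrays gave 95.0% to 97.6% and 84.6% to 95.9%. The brain share estimated from features at least 4-fold apart was above the labelled share. The mixture labelled 33% brain gave 44.8% ± 0.643 with WT PLUS and 55.0% ± 1.32 with Ovation Pico (SD, n = 2), and the one labelled 67% gave 74.6% ± 3.77 and 82.0% ± 4.40. The first Ovation Pico value was 61.1% without all blood replicate 1 and 45.0% without all blood replicate 2.

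**Figure D3:**
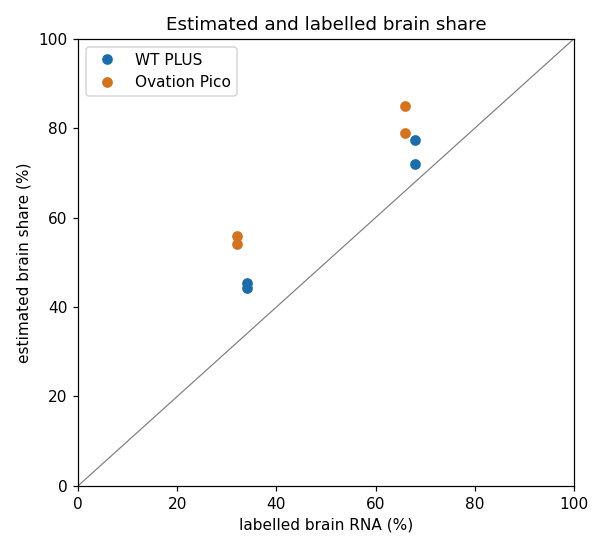
Brain share estimated from each mixture array against the labelled share, in percent, 2 arrays per mixture and kit, shifted slightly sideways, with the line of equality. All 8 points lie above the line.

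The last comparison asked whether the change from blood to brain depends on the kit. The genes with the largest differences changed with 1 kit far more than with the other. PEG3-AS1, an antisense transcript named for the imprinted gene PEG3, rose by 5.40 ± 0.167 with Ovation Pico, from 3.39 to 8.79, but its WT PLUS signals were 2.32 in blood and 2.98 in brain. These and the WT PLUS signals of GK-AS1 (2.33 and 2.07) lie under the mean of the antigenomic background features on the same arrays (4.23 and 4.30 in blood, 3.92 and 3.98 in brain), so neither gene is shown to be above background with that kit and the size of their kit differences is uncertain. HEPN1 differed by 4.49 ± 0.233 (0.98 with WT PLUS, from 3.30 to 4.27, the blood value also under that mean). RPRML was at 3.04 with Ovation Pico and 0.04 with WT PLUS, CCNI2 at 2.72 and 0.02 (4.02 in blood with WT PLUS, again under that mean), and TCEAL5 at 4.67 and 2.10. USP17L6P, of a family with many near-identical copies, rose with Ovation Pico and fell by 1.25 with WT PLUS, a difference of 2.75. The reverse held for the synapsin gene SYN1, which rose by 4.86 with WT PLUS and 1.82 with Ovation Pico, a difference of −3.04 ± 0.192 (adjusted p = 4.74e-06), and for the protocadherin PCDHGC5 at 4.16 and 0.79, whose exons are shared within its gene cluster. A2M, a protease inhibitor, was at 2.63 and −0.09, GPR158 at 4.25 and 1.91, RGS4 at 4.26 and 1.97 (these 2 and PCDHGC5 under the antigenomic mean in WT PLUS blood), and GK-AS1 at −0.26 and −2.68, a difference that did not pass without WT PLUS all blood replicate 1 or with the kind of array as a block (adjusted p = 0.205). The strand measured by each feature is not given in the table, so antisense and overlapping genes are uncertain.

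Several brain cell lists rose less and several blood cell lists fell less with Ovation Pico by camera with the preset correlation. Changes were smaller with that kit over all features too (slope 0.852, and over features with 1 symbol an SD of 0.763 against 0.966). Lists with large rises or falls can therefore differ this way without a difference particular to their cells. The list differences were not set against that general one. None of the lists passed with an estimated correlation, where the adjusted p of those that passed before ran from 0.0718 for B cells to 0.506 for neutrophils. As differences between kits (Ovation Pico minus WT PLUS), the medians were −0.41 for neurons (adjusted p = 3.25e-05), −0.97 for glutamatergic genes (adjusted p = 1.10e-08), −0.47 for astrocytes (adjusted p = 0.00148) and −0.27 for oligodendrocytes (adjusted p = 0.00114). For the blood they were 0.71 for T cells (adjusted p = 2.53e-06), 0.53 for B cells (adjusted p = 0.000187), 0.69 for red cell precursors (adjusted p = 0.000378), 0.52 for platelets (adjusted p = 0.00114), 0.61 for globins (adjusted p = 0.0167) and 0.54 for neutrophils (adjusted p = 0.0252). GABAergic neurons (−0.37, adjusted p = 0.0983), microglia (0.10, adjusted p = 0.266), monocytes (0.72, adjusted p = 0.0643), and natural killer and eosinophil lists (0.37 and 0.47, both with adjusted p = 0.112) did not pass. Of 19 neuron genes 6 had a significantly smaller and 2 a larger rise with Ovation Pico, or 8 and 2 adjusted over the list alone. Of 16 T cell genes 8 fell significantly less, or 12 adjusted over the list alone. Signed differences (Ovation Pico minus WT PLUS) were significantly lower for 7 and higher for 0 of 13 glutamatergic genes, 2 and 1 of 12 astrocyte genes and 5 and 0 of 14 oligodendrocyte genes. Adjusted over each list alone these counts were 9 and 0, 7 and 2, and 7 and 0. Signed differences were significantly higher for 5 and lower for 2 of 17 neutrophil genes, and higher for 5 of 10 B cell, 5 of 12 red cell precursor, 4 of 11 platelet and 2 of 5 globin genes, with 0 lower. Adjusted over each list alone, 3 neutrophil genes and 1 globin gene were lower, and 6 red cell precursor and 7 platelet genes were higher. The globin value includes HBB, whose falls are lower bounds, so the size of its difference is not known. In all 16 of 29 lists passed, 7 up and 9 down in signed difference. Apart from the estimated correlation, 7 of the 16 lost their call or changed the sign of their median in at least 1 setting. Neutrophils, oligodendrocyte precursors and cerebellum did not pass without Ovation Pico all blood replicate 1, nor did oxidative phosphorylation and hypothalamus without its all blood replicate 2, or hypothalamus without its all brain replicate 2. Medians of vessel cells and small nucleolar RNAs changed sign with housekeeping centring, to 0.0166 and 0.0494. Both lists still passed by camera there (adjusted p = 0.0272 and 6.08e-08), while hypothalamus did not. With the kind of array as a block hypothalamus did not pass either (adjusted p = 0.208), while monocytes, natural killer cells and interferon response did. That block moved 4 of the 16 medians by over 1.5 times: neurons to −0.22, red cell precursors to 0.45, vessel cells from −0.12 to −0.18 and small nucleolar RNAs from −0.0858 to −0.34. The histone, striatal and ribosomal lists, which did not pass, had medians and means of opposite sign.

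Over all features, 3943 had a brain minus blood change that differed between kits. The change was larger in size with WT PLUS for 2757 and with Ovation Pico for 1186. The count was 572 with the kind of array as a block, 2146 with housekeeping centring (33.2% lower, against 43.9%), 10645 and 6113 without Ovation Pico all blood replicate 1 and 2, 1896 and 2258 without its all brain replicate 1 and 2, and 2146, 1861 and 2418 without WT PLUS all blood replicate 2 and all brain replicates 1 and 2. The SD of the brain minus blood changes was 0.795 with WT PLUS and 0.698 with Ovation Pico, and single pairs of arrays gave 0.786 to 0.830 and 0.705 to 0.764. The middle 98% of changes ran from −2.53 to 2.76 and from −2.29 to 2.31. The slope of Ovation Pico on WT PLUS changes was 0.852 (0.812 to 0.963 for single pairs of arrays), with r = 0.809 and rho = 0.631 across features, which are not independent replicates.

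Both kits called 4425 features as higher and 5325 as lower in brain, where independent lists of these sizes would share 681.4 and 2536. Another 95 were called in opposite directions. Of the features called with Ovation Pico 82.8% were called the same way with WT PLUS, and 28.0% of those called with WT PLUS were called the same way with Ovation Pico. Without Ovation Pico all brain replicate 1 or 2, 5473 or 5340 features were called the same way in both kits instead of 9750.

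**Figure D4:**
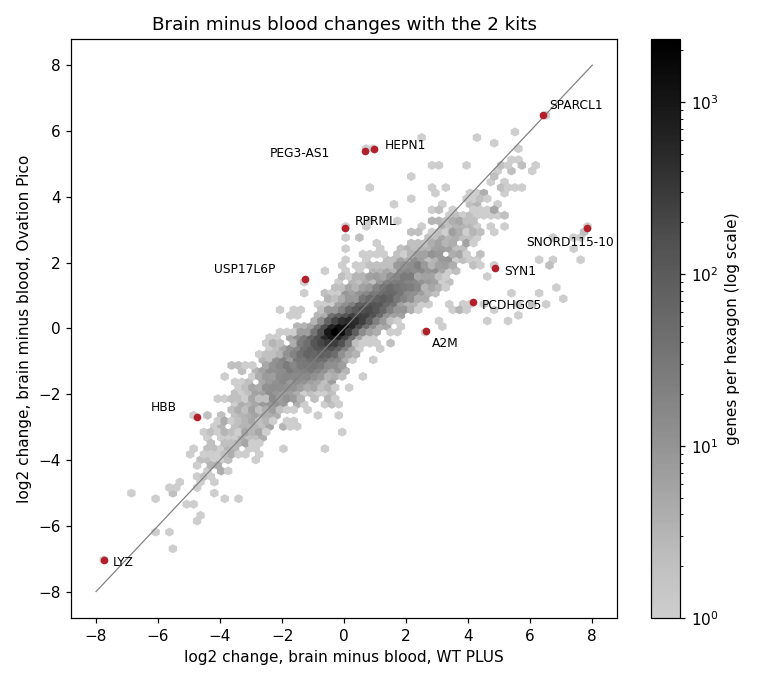
Log2 change from blood to brain with Ovation Pico against that with WT PLUS for named genes as shaded hexagons (genes per hexagon on a log scale), with 11 genes marked and the line of equality. PEG3-AS1 and HEPN1 lie far above the line, and SYN1, PCDHGC5 and SNORD115-10 far below it.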

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

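Of the tests in this part, those of the background features, of the arrays without hybridization controls and of 1 constant per array were chosen only after the result was seen. The change from blood to brain differed between the kits for 3943 features by limma's interaction term.

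Lists whose change differed between kits, by the same term and camera, had these median differences (Ovation Pico minus WT PLUS): neurons −0.41, glutamatergic neurons −0.97, astrocytes −0.47, oligodendrocytes −0.27, oligodendrocyte precursors −0.25, vessel cells −0.12, cerebellum −0.38, hypothalamus 0.34, globins 0.61, red cell precursors 0.69, neutrophils 0.54, T cells 0.71, B cells 0.53, platelets 0.52, oxidative phosphorylation −0.18 and small nucleolar RNAs −0.0858. None of these lists passed with an estimated correlation (adjusted p from 0.0718 to 0.506). That aside, 7 of the 16 lost their call or changed the sign of their median in at least 1 alternative. They were not set against the generally smaller changes with Ovation Pico. In the hypothalamus list 0 of 9 genes passed on their own. The antigenomic background features also fell more with WT PLUS (median −0.22, against −0.06 with Ovation Pico), so that list's difference is not shown to be one of its RNAs.

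Among the named genes, the same term gave higher values with Ovation Pico for PEG3-AS1 (4.74), HEPN1 (4.49), RPRML (3.00), USP17L6P (2.75), CCNI2 (2.70), TCEAL5 (2.56), HBB (2.06), ALAS2 (1.72), SLC4A1 (1.69), CD79A (1.56), NEFM (1.51), CFAP126 (1.47), HBZ (1.26), TYROBP (1.10), PF4 (0.96) and PVALB (0.57). It gave lower values for SNORD115-10 (−4.79), SNORD115-6 (−4.76), PCDHGC5 (−3.37), SYN1 (−3.04), A2M (−2.72), GK-AS1 (−2.42), GPR158 (−2.34), RGS4 (−2.29), GZMA (−1.86), TNR (−1.52), GABRA6 (−1.49), RELN (−1.35), ATRNL1 (−1.24), KIF5A (−1.22), ZIC2 (−1.10), RGS5 (−1.07), MNDA (−1.03), LHFPL3 (−0.77), MOBP (−0.76) and UGT8 (−0.76). The value of HBB compares 2 lower bounds, since its signal hardly moved while any blood was present, and does not show a smaller fall with Ovation Pico. PEG3-AS1, PCDHGC5, GPR158, RGS4, HEPN1, CCNI2, RELN, UGT8, GABRA6, LHFPL3 and CFAP126 in WT PLUS blood, ATRNL1 and SNORD115-10 in blood with both kits, MNDA and GZMA in WT PLUS brain, and GK-AS1 in brain with both kits lay under the mean of the antigenomic background features, so the sizes of their differences are uncertain.

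PEG3-AS1 and GK-AS1, named as antisense transcripts, had their changes mainly with Ovation Pico and are not shown to be above background with WT PLUS. Larger changes of all genes with that kit are excluded as the cause, since the median absolute change over genes was 0.603 times that with WT PLUS. Signal from the gene on the opposite strand may contribute: over 681 pairs of a gene and its antisense namesake, the changes of the partners correlated with rho = 0.452 with Ovation Pico and 0.286 with WT PLUS, a difference of 0.165 (0.0890 to 0.240, the 95% range of 10000 resamplings of pairs, which are not independent). The test set beforehand asked for more than 0.2 in favour and at most 0.05 against, and the value lies between, so this stays open. No biological explanation was tested, since the design names none for a difference between kits.

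With WT PLUS 74.4% of the changed features were lower in brain, 94.8% among the 16882 dimmest and 55.9% among the 16882 brightest. Whether the arrays without hybridization control signal account for part of it stays open. With them as a block 58.1% were lower. From all blood to 67% blood, where all 4 arrays have that signal, 76.8% were lower, but under 65% without either 67% blood array. More than 65% was to speak against. This test was extended to the arrays left out only after the 76.8% had been read as against. These percents cannot decide it, since most calls as lower were small changes, which any loss of power removes first. Among at least 2-fold changes 52.4% were lower from all blood to all brain, and 10.6% from all blood to 67% blood. The median change of all features was −0.22 and −0.19 over these steps, so a fall of the median was present without those arrays. A shift of whole arrays by 1 constant met the test written beforehand, with 51.8% lower after quantile normalization, but that method forces 1 distribution on the arrays whatever the cause; a replacement test, chosen after that result, speaks against 1 constant as the whole cause, since the changes of the 23 background features spanned 0.582, from −0.07 to −0.65, against replicate differences with an SD of 0.0669 in blood and 0.0903 in brain. Higher non-specific signal on the blood arrays is a candidate explanation: all 23 background features were lower in brain, with a median of −0.22, against −0.06 with Ovation Pico. A true difference between the tissues stays open and was not tested.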

How the results depend on the processing

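The block of arrays without hybridization control signal and the brightest 25% of features were chosen only after the data were seen. Where a left-out array leaves 1 array in a group, that array is assumed to vary like the other groups. With 2 arrays per group the counts of changed features were unstable. They include dim features near the background, whose part in this was not tested. An estimated correlation left 0 lists past the threshold in each kit and in the difference between kits. That setting rests on few degrees of freedom and does not decide whether the list calls hold. That aside, a call held if it passed with the same direction in every alternative. The direction of a list is the sign of its median. For genes named for other reasons than a kit difference, 78 of 103 calls with WT PLUS and 69 of 78 with Ovation Pico held. So did 11 of 12 in the difference by the rule for kit differences, and 20 of 23, 17 of 21 and 9 of 16 lists.

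For brain minus blood with WT PLUS, 34811 features became 7612 with a 2-fold minimum, 15017 with 1 symbol, 12033 in the brightest 25%, 11947 with the control block, and 22100 to 34700 with an array left out. With Ovation Pico, 11774 became 6033, 5839 and 7046 under the first 3 of these, 7163 from the 4 arrays alone, and 6088 to 17550 with an array left out. Fewer features were tested with 1 symbol or in the brightest 25%. Fewer arrays were fitted when 1 was left out, but the Ovation Pico count could then also rise, so the number of arrays alone does not account for these moves. Ovation Pico contrasts that use no all-blood array also rose in count, equally, when either all-blood array was left out. Their log2 changes do not depend on those arrays, so there only the estimated residual spread had moved. The cause of the other changes was not tested.

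Along the mixtures with WT PLUS, 67% blood minus all blood gave 11826 with quantile normalization, 1899 with a 2-fold minimum and 7731 to 20382 with an array left out. From 67% to 33% blood these were 104 with a 2-fold minimum and 0 to 2219. From 33% blood to all brain a 2-fold minimum gave 818. All blood to 33% blood gave 21636 in the brighter 50%, 20192 with quantile normalization, 5105 with a 2-fold minimum and 18348 to 31100 with an array left out. For 67% blood to all brain the last 2 gave 2241 and 6504 to 10916. With Ovation Pico, 67% blood minus all blood gave 1644 with a 2-fold minimum and 1132 to 13741 with an array left out, and 67% to 33% blood 0 to 271. From 33% blood to all brain 219 were called in the brighter 50%, 321 with quantile normalization and 17 to 600 with an array left out. All blood to 33% blood gave 4197 with a 2-fold minimum and 3003 to 15992. From 67% blood to all brain the brighter 50% gave 2043, quantile normalization 1959, and leaving out an array 224 to 4497.

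The SD of brain minus blood changes was 1.07 in the brighter 50% and 0.966 with 1 symbol with WT PLUS (0.781 to 0.821 with an array left out), and 0.942 and 0.763 with Ovation Pico (0.698 to 0.758). Mixture order held for 96.8% to 98.9% and 90.4% to 97.1% with an array left out. The brain share of 67% blood with WT PLUS was 41.9% from 16-fold features, 48.7% with housekeeping centring and 43.3% to 46.5% with an array left out. With Ovation Pico it was 51.8% with quantile normalization, 53.3% from 16-fold features and 45.0% to 61.1%. The slope was 0.768 with 1 symbol and 0.819 to 0.939 with an array left out. Features changed the same way in both kits were 4367 with a 2-fold minimum and 5340 to 13152. Those that differed between kits were 2024 with a 2-fold minimum, 1826 with 1 symbol, 2146 with housekeeping centring, 572 with the control block and 1861 to 10645 with an array left out.

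The WT PLUS median of small nucleolar RNAs turned to −0.15 with housekeeping centring, −0.028 with the mean of a gene's features and −0.033 without all brain replicate 2 (−0.033 to 0.0867 over the arrays left out). Their difference between kits turned to 0.0494 with housekeeping centring, 0.0017 without WT PLUS all brain replicate 2 and 0.0448 without Ovation Pico all blood replicate 2 (−0.181 to 0.0448 over the arrays left out). That of vessel cells turned to 0.0166 with housekeeping centring, and that of ribosomal proteins to −0.143 without Ovation Pico all blood replicate 1 (−0.143 to 0.194 over the arrays left out). Housekeeping centring moves the change of every feature by the same amount, so it can turn the sign of a small median. The cause of the other turns was not tested.

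Replicate numbers did not pair the arrays: deviations of same-numbered arrays correlated at −0.364 to 0.146 with WT PLUS, −0.452 to 0.338 with Ovation Pico and −0.292 to 0.0304 between kits. With the number as a block, brain minus blood gave 32116 and 9850 features with WT PLUS and Ovation Pico, and the difference between kits 3299. The block moved 3 counts by over 1.5 times: WT PLUS 67% to 33% blood to 1514, Ovation Pico 33% blood to all brain to 83 and 67% blood to all brain to 708.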

Other observations

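All tests of the brain share in this part, and the small nucleolar RNA families, were chosen only after the result was seen. Small nucleolar RNAs of 2 imprinted regions rose in brain. Of 31 SNORD115 copies 30 rose with WT PLUS and 22 with Ovation Pico, and of 19 SNORD116 copies 18 and 14, both from the region lost in Prader-Willi syndrome. Of 31 SNORD114 copies 26 and 21 rose, and of 9 SNORD113 copies 8 and 4, both from the imprinted DLK1 and MEG3 region. In these 4 families 0 members fell with either kit. Of the other 147 small nucleolar RNAs, 12 rose and 74 fell with WT PLUS (median −0.51, against −0.22 for all features), and 7 rose and 23 fell with Ovation Pico (median −0.31, against −0.10). Of these 147, 37 in blood and 44 in brain lay under the antigenomic mean with WT PLUS, and 42 and 57 with Ovation Pico. An antigenomic feature near their median WT PLUS level (5.84 in blood, 5.25 in brain) fell by 0.654, so their lower median is not shown to be a fall of these RNAs.

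Some members of each family had changes that differed between kits, most often in SNORD115. The families as such were not tested. The median change of SNORD115 copies was 5.99 with WT PLUS (0.29 to 7.85) and 0.73 with Ovation Pico (−0.11 to 3.05), and 28 of 31 had a significantly smaller change with Ovation Pico. With Ovation Pico 28 of the 31 lay under the mean of the antigenomic background features in blood and 19 also did in brain, against 24 and 4 with WT PLUS, so the smaller changes are not shown to be smaller changes of the RNA. The other families are limited too. Under that mean in brain lay 8 of 19 SNORD116 copies with Ovation Pico, against 4 with WT PLUS. For SNORD114 it was 16 of 31 against 15, and for SNORD113 4 of 9 with each kit, so these 2 families are limited alike with both kits. For SNORD116 the medians were 2.27 and 1.23, with 8 significantly smaller and 1 larger. For SNORD114 they were 1.22 and 0.80, with 9 smaller and 1 larger, and for SNORD113 0.91 and 0.45, with 2 smaller and 1 larger. Copies within a family are similar in sequence, so their features are not independent.

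The estimated brain share exceeded the labelled share in both kits. Compression of high signals would place the share from blood-high features under the labelled 33% in the first WT PLUS mixture. A single scaling factor on the mixture arrays would place the shares from blood-high and brain-high features on opposite sides of 33%. Both shares were above it, at 43.6% ± 1.44 (SD, n = 2) from blood-high and 46.1% from brain-high features. This covers the median of these features, not single bright genes such as HBB. A candidate explanation is that brain RNA gives more signal on the array per unit than blood RNA, for which a single ratio would serve both mixtures of a kit: the estimated over the labelled brain to blood ratio was 1.65 and 1.45 with WT PLUS, 1.14 times apart, and 2.48 and 2.24 with Ovation Pico, 1.11 times apart. These ratios are imprecise, since brain-high features gave 74.4% ± 9.72 for the mixture labelled 67% with WT PLUS, and the first Ovation Pico share was 61.1% or 45.0% without all blood replicate 1 or 2. Errors in mixing were not tested, nor was a biological explanation.

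The median ratio of the Ovation Pico to the WT PLUS change was 0.810 for features called higher in brain by both kits and 0.957 for those called lower by both. Features that pass in both kits favour large Ovation Pico changes, and over all genes with 1 symbol the ratio of the median absolute changes was 0.603. That ratio includes the shift of all features, whose median change was −0.22 with WT PLUS and −0.10 with Ovation Pico. The SD of the changes, which such a shift does not alter, was 0.763 with Ovation Pico and 0.966 with WT PLUS over features with 1 symbol.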
